A study of Mus musculus with 5 samples.

How the data were processed

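Gastrocnemius muscle of mice injected with extracellular vesicles was measured by RNA sequencing in 5 samples of 1 group. Per the labels' protocols, RNA was extracted from about 20 mg of homogenised tissue with Trizol, messenger RNA was purified on poly-T beads and fragmented, and the libraries were made and sequenced by a commercial provider. Selection on poly-A tails limits the measurement mostly to polyadenylated transcripts. The submitters' processing notes name TopHat, STAR 2.5, HTSeq 0.6.1, DESeq2, edgeR and the mouse genome build mm10, without a role or order for each. The annotation release, the strand setting, the treatment of reads that match several genes and whether reads or read pairs were counted are not given in the sources used here.

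The deposited table gives FPKM values per gene and library, which the authors computed from reads per gene, gene length and library total, as the steps of the values themselves show. In each library the values of a gene are whole multiples of what 1 read is worth. Library totals were found as the commonest value that made the lowest genes whole at their annotated exon length, and a gene length was then sought that made the values of all 5 libraries whole reads within 0.001 of a read. This worked for 20838 of 20840 genes above 0 (99.99%), of which 15694 were above 0 in all 5 libraries; genes above 0 in few libraries meet the criterion more easily. The recovered reads summed to 98.4% ± 0.148 of the library totals (SD, n = 5). Of the 20838 genes, 4544 were whole at their annotated exon length, and for the others the reads rest on the length found. Within that limit the depth behind the values can be estimated, and 3 reads correspond to 0.118 to 0.180 reads per 1e+06 reads of a library. Intervals and such floors cover counting error only, since reads copied in the amplification of a library are not independent molecules. FPKM divides by the library total, so a few abundant genes that take more of a library lower all others in it. No columns of other samples were used.

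Of 35275 gene identifiers, 34490 were matched to symbols and to the GENCODE M21 annotation of GRCm38, the assembly that mm10 also names, from which chromosome, start and end were taken. The identifiers of the table end partway through that annotation, so that 15196 of its 55450 genes, 554 of them protein coding, have later identifiers and were not analysed here.

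The design had assumed that the table might hold counts or normalized values and named a test for each. The table holds FPKM, so the test for normalized values was used, and the count test named in the design was not run. A fit with voom weights, a method for counts, was added later on the recovered reads as an alternative. Genes at a mean of 1 FPKM or more (10710) were tested on the log2(FPKM + 1) scale with limma 3.58.1 in R 4.3.3. An intercept was fitted, the variance of each gene was divided by its abundance trend, and the ratio was compared with the F distribution with 4 and 3.93 degrees of freedom (one-sided, Benjamini-Hochberg adjustment, threshold 0.05). The test was checked on data simulated for the same 10710 genes, in which 200 genes were given a larger SD. Of these, 13%, 50%, 77% and 82% were among the 200 genes with the largest ratio at 2, 4, 8 and 64 times the SD, but the adjusted p recovered 0%, 0%, 0% and 51%, with 0 false calls.

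Before the data were examined, 49 gene lists were fixed, 31 of pathways and responses and 18 of cell type markers, with 634 different genes in the table. A list score in a library is the mean over its genes at 1 FPKM or more of the log2(FPKM + 1) value minus the mean of that gene over the 5 libraries, for the 40 lists with at least 4 such genes. The SD of a score over the 5 libraries was ranked among 10000 random lists with the same number of genes, drawn from 20 bins of mean level. Such a percentile describes these libraries and is not a p-value. The genes of a list can vary together for many reasons, and real lists can exceed random ones for that alone. Shares of 6 myosin heavy chain genes were taken from summed FPKM, with Wilson intervals at 95% from recovered reads. The 13 within-library ratios were tested with an exact two-sided sign-flip permutation test over 32 sign patterns. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

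The genes named were chosen by a rule fixed in advance, which took the 3 members with the highest mean of each list, both members of each ratio, all strain and sex checks, the 15 most abundant genes, and, among genes past the threshold for varying between libraries, the 20 with the largest ratio of spread to trend. No gene passed that threshold, so the 20 were taken without it, a change made after the values were seen. The rule named 185 genes, most of which are given with values. Another 17, list members used as examples among them, were chosen after their values were seen. Alternatives covered the pseudocount, the filter on low values, the scaling of libraries, the mean or median over a list's genes, the prior of the variance and each library left out in turn. On the scale with a pseudocount, differences of genes near 1 FPKM are understated.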

Results

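Messenger RNA of the gastrocnemius, a mainly fast-twitch muscle of the calf, was sequenced from female NSG mice at an age of 12 weeks. NSG mice are an immunodeficient strain that carries the scid allele of Prkdc and a null allele of Il2rg and lacks mature T, B and natural killer cells. The mice had received 10 injections into the tail vein, 2 per week for 5 weeks, each with about 10 µg of extracellular vesicles from cells labelled MCF-10A/miR122. MCF-10A is a non-tumorigenic human mammary epithelial cell line, and miR-122 is a microRNA known for its abundance in liver. Muscle was taken 2 days after the last injection. The labels give 5 samples, numbered 1 to 5, in 1 group, so the values below describe the transcript levels of the treated muscle and how far the 5 libraries lay apart, and no treated library was set against an untreated one. The labels do not say outright that each number is a separate animal, so every spread given here is the spread between these 5 samples.

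The libraries held 22922332, 18533514, 16674504, 23826585 and 25407988 reads in the order of their numbers. The level of each gene is given in FPKM, its reads scaled by the length of the gene and the total of the library. Of 35275 genes in the table, 9678 reached 1 FPKM in all 5 libraries, of which 9323 were annotated as protein coding, and 11708 reached it in at least 1 library. A gene at 1 FPKM or more on average had a median of 394 reads per library. The median coefficient of variation of these genes between libraries was 16.3%, against 5.04% from counting error, and 9409 of 10709 genes (87.9%) varied by more than counting error in a chi-square test with Benjamini-Hochberg adjustment.

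The most abundant transcripts were those of the fast contractile apparatus and of mitochondria. Acta1, the skeletal muscle alpha-actin (ENSMUSG00000031972, chromosome 8, 123891769 to 123894751), stood first at 32368 ± 1983 FPKM (SD, n = 5) and took 4.71% ± 0.288 of the reads. It was followed by mt-Co1, a mitochondrially encoded subunit of cytochrome c oxidase, at 20437 ± 2968 FPKM, and by the fast troponin T gene Tnnt3 at 15842 ± 3062 FPKM. The glycolytic aldolase Aldoa reached 14476 ± 2208 FPKM. The other 11 of the 15 most abundant genes were mt-Nd1, mt-Cytb, Mylpf, Tnni2, Atp2a1, mt-Nd2, Pvalb, Myh4, Ckm, Myl1 and mt-Nd4. The 10 most abundant genes of a library took 24.4% ± 2.20 of its reads, and genes of the mitochondrial genome took 8.69% ± 0.936.

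Library 3 stood apart from the other libraries over the whole transcriptome in correlation and in the first principal component. Pearson's r across genes on the log2(FPKM + 1) scale was 0.961 to 0.970 for the 4 pairs with library 3 and at least 0.981 for the other pairs, with a median of 0.982 over all 10 pairs; genes are not independent replicates in such a correlation. The first principal component held 52.6% of the variance and placed library 3 at 36.0, with the other libraries between -14.6 and 2.20. The second held 23.2% and placed library 2 farthest out, at 19.2. Every pair of libraries differed by more than counting error, with a chi-square per gene of 25.6 to 133. The largest values were those of library 2 with libraries 4 (133) and 5 (110), against 73.1 to 102 for the pairs with library 3. By that measure, in which genes with many reads weigh most, library 3 was not the farthest apart.

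Genes of muscle protein breakdown were measured at moderate levels. Among the ubiquitin ligases, Trim63 (MuRF1), which marks sarcomere proteins for the proteasome, was at 132 ± 32.8 FPKM, Fbxo32 (atrogin-1) at 31.6 ± 7.51, Asb2 at 169 ± 41.0 and Nedd4 at 78.8 ± 7.93 (SD, n = 5). The score of the list of 22 ubiquitin ligase and atrophy genes, which is the mean over its genes of the deviation from each gene's own mean on the log2(FPKM + 1) scale, had an SD of 0.04 over the 5 libraries. That lay at percentile 5.59 of random gene lists matched on size and mean level, at 83.8 under median-of-ratios scaling of the libraries, at 52.4 with members at 10 FPKM or more and at 1.07 (without library 1) to 14.4 (without library 5) with 1 library left out. Its members went different ways, as in library 3, where Mt2 was highest at 94.8 FPKM against 5.73 to 35.6 and Fbxo32 lowest at 18.9 against 31.2 to 38.03. The 23 autophagy and lysosome genes had an SD of 0.06 (percentile 32.7), which was 0.03 without library 5 (percentile 7.75), and lay at percentile 53.6 without library 3, 63.2 under median-of-ratios scaling and 70.5 with the median over members, with Pink1 at 438 ± 64.1 FPKM, Ctsd at 246 ± 48.4 and Sqstm1 at 198 ± 28.5. The 8 genes of calpains, their regulators and caspases had an SD of 0.20 (percentile 94.7, and 97.0 with the median over members), with Capns1 at 142 ± 18.8 FPKM. The 31 proteasome subunits were highest in library 3 for 25 genes and in library 4 for 6, with an SD of 0.16 (percentile 99.8), and Psmb7 ranged from 179 to 230 FPKM, Psmb6 from 143 to 187 and Psma6 from 106 to 149. Under median-of-ratios scaling the proteasome score was highest in library 4 in place of library 3.

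The O-GlcNAc cycle adds a sugar to proteins through Ogt and removes it through Oga, and Ogt is among the published targets of miR-122. Ogt (chromosome X, 101640060 to 101684351) was at 13.4 ± 3.07 FPKM and Oga, annotated as Mgea5, at 7.09 ± 1.01 (SD, n = 5). Gpi1, shared with glycolysis, was the most abundant gene of the hexosamine list at 318 ± 30.4 FPKM, and Uap1 was at 17.4 ± 2.05. Gfpt1 and Gfpt2, which make the first committed step of the pathway, were at 6.09 ± 0.949 and 4.46 ± 1.07 FPKM. The 8 measured genes of the list lay at percentile 30.4 of the random lists, and at 69.0 with the median over members. Of the published miR-122 targets, 18 were measured, the most abundant being Aldoa, the pyruvate kinase Pkm at 2075 ± 204 FPKM and the citrate synthase Cs at 316 ± 45.7, followed by Ccng1 at 276 ± 32.4. As a list they lay at percentile 64.3, at 10.6 without library 4 and at 21.9 with members at 10 FPKM or more, with scores from -0.16 in library 4 to 0.10 in library 3. Levels in treated muscle alone do not show whether any of these genes was repressed.

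Calcium handling genes were among the most abundant of the tissue. Atp2a1, the fast calcium pump SERCA1, was at 8609 ± 778 FPKM, the calcium buffer Pvalb at 7799 ± 2621, the calcium store protein Casq1 at 1115 ± 231, the release channel Ryr1 at 345 ± 39.3 and its voltage sensor Cacna1s at 207 ± 14.3 (SD, n = 5). The 22 genes of the list lay at percentile 53.5, at 22.9 without library 3 and at 89.2 with the median over members. The 15 glycolysis genes lay at percentile 61.7, at 10.2 without library 2 and at 93.2 under median-of-ratios scaling, with Gapdh at 5637 ± 705 FPKM and Eno3 at 4920 ± 538. The 18 genes of insulin and growth signalling lay at percentile 44.6, at 28.8 without library 4 and at 79.2 under median-of-ratios scaling, with Akt2 at 60.7 ± 3.66 FPKM, Akt1 at 33.7 ± 7.60 and Eif4ebp1 at 40.3 ± 10.6. The 16 circadian clock genes lay at percentile 50.1, at 98.2 under median-of-ratios scaling and at 3.94 without library 5, with Bhlhe40 at 62.6 ± 9.52 FPKM, Dbp at 62.2 ± 8.64 and Tef at 56.9 ± 6.80. The 13 genes of the unfolded protein and integrated stress response lay at percentile 0.26, and at 0.27 to 1.17 with 1 library left out. They lay at 46.4 under median-of-ratios scaling and at 67.3 with the median over members. Calr was at 94.3 ± 19.3 FPKM, Atf4 at 74.8 ± 8.83 and Hspa5 at 72.5 ± 17.5. Members went different ways in library 3, where Calr was highest at 127 FPKM against 77.4 to 92.7 and Atf4 lowest at 63.5 against 72.3 to 88.1. The 10 hypoxia genes lay at percentile 88.7, at 60.6 without library 2, at 97.9 without library 3 and at 98.5 with the median over members, with Bnip3 at 75.8 ± 13.8 FPKM, Vegfa at 70.4 ± 17.9 and Egln3 at 43.0 ± 8.16.

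Within a library, 12 of 13 gene pairs kept the same order in all 5 libraries. Fbxo32 lay below Trim63 by a log2 ratio of -2.03 ± 0.33, Foxo1 below Foxo3 by -0.45 ± 0.17 and the growth factor Igf1 below the growth inhibitor Mstn by -1.66 ± 0.74 (SD, n = 5, on the log2(FPKM + 1) scale). Ogt lay above Oga by 0.82 ± 0.27, Gfpt1 above Gfpt2 by 0.39 ± 0.32, Ryr1 above Cacna1s by 0.73 ± 0.09, Capn3 above Capn1 by 0.91 ± 0.18 and the receptor subunit Il6st above Il6ra by 3.09 ± 0.23. Without library 1 the ratio of Gfpt1 to Gfpt2 was 0.25. Counted in reads, which are not corrected for gene length, Fbxo32 exceeded Trim63 in libraries 2 and 5. The fast-muscle forms exceeded their slow-muscle counterparts, by 5.69 ± 0.94 for Atp2a1 over Atp2a2 and by 3.72 ± 0.85 for Ldha over Ldhb. Myh4 exceeded Myh1 by 2.75 ± 1.25. Pklr, the liver and red cell pyruvate kinase, was listed at 0 in all 5 libraries, against 2075 ± 204 FPKM for Pkm, and no ratio is given for that pair. Myh1 exceeded Myh2 by 0.40 ± 0.36 and did so in 4 of 5 libraries (p = 0.125, exact sign-flip permutation test, two-sided). For each of the other pairs the exact test gave p = 0.0625 (0.0677 after Benjamini-Hochberg adjustment over the 13 pairs), the smallest p that 5 samples allow, so none could pass 0.05.

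Fast type IIB myosin made up most of the myosin heavy chain transcripts, and library 2 held the largest share of slower types. Myh4, the type IIB isoform (ENSMUSG00000057003, chromosome 11, 67238029 to 67260446), took 75.9% ± 15.6 of the summed FPKM of 6 isoforms (SD, n = 5). Myh1 (type IIX) took 13.1% ± 8.98, Myh2 (type IIA) 9.39% ± 5.70, Myh7 (type I, chromosome 14, 54970684 to 54994626) 1.45% ± 1.19, the embryonic Myh3 0.0634% ± 0.0799 and the perinatal Myh8 0.0172% ± 0.0110. The mean share of Myh7 was 0.924% without library 2, and that of Myh3 0.0286% without library 3. The share of Myh4 was 50.6% in library 2 and 71.3% in library 3, against 84.6%, 87.4% and 85.8% in libraries 1, 4 and 5. Library 2 also had the highest share of Myh1 (26.6%), Myh2 (19.2%) and Myh7 (3.55%). Counting error was far smaller than these gaps, since the share of Myh4 among the myosin reads of library 2 was 50.3% with a 95% Wilson interval of 50.2% to 50.4%, which covers counting error only. These isoforms are similar in sequence, and how reads that match several of them were assigned is not given in the sources used here.

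**Figure D1:**
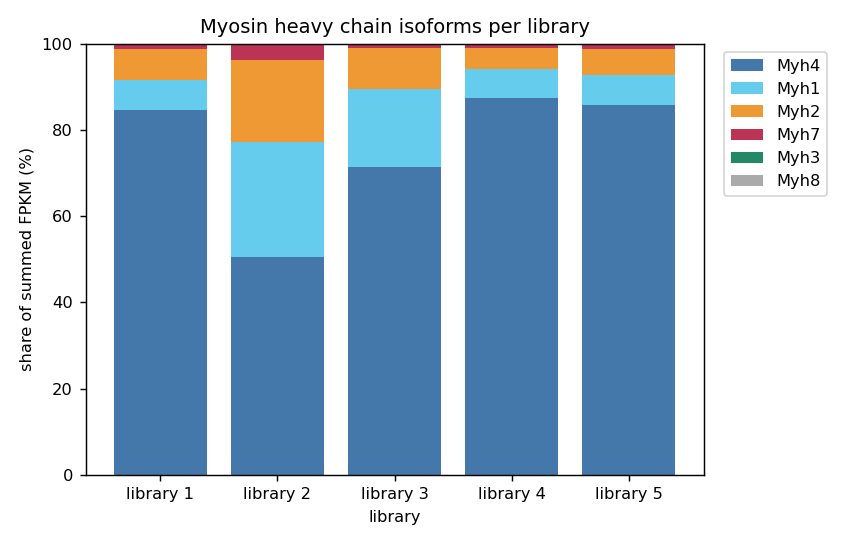
Share of 6 myosin heavy chain isoforms in their summed FPKM (vertical axis, percent) for each of the 5 libraries (horizontal axis); each coloured segment is 1 isoform. Myh4 took 50.6% in library 2 and 71.3% in library 3, and between 84.6% and 87.4% in the other libraries.

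The slow fibre program as a group was highest in library 2. Of 12 slow sarcomere genes, 11 had their highest level there, with a list score of 1.08 in library 2 and scores from -0.48 to -0.14 in the other libraries (SD 0.62, percentile 100). The slow troponin T gene Tnnt1 was at 975 FPKM in library 2 against 294 to 415 elsewhere, Myl2 at 744 against 131 to 302, Tnnc1 at 661 against 246 to 286 and Atp2a2 at 433 against 99.4 to 185. Actn2, the gene of the list with the highest mean, was nearly as high in library 3 (953 FPKM) as in library 2 (987), against 411 to 463 in the others. All 6 genes of the marker list for an adjacent slow muscle, the soleus, which are also in the slow sarcomere list, were highest in library 2 (SD 0.70, percentile 100). Without library 2 the lists fell to percentile 92.0 and 94.0. Most genes of oxidative metabolism were also highest in library 2, namely 16 of 20 in the tricarboxylic acid cycle (percentile 99.6), 18 of 25 in fatty acid uptake and oxidation (percentile 100) and 17 of 24 in nuclear oxidative phosphorylation (percentile 99.5). Examples are Sdhb at 496 FPKM in library 2 against 347 to 443 and Lpl at 243 against 112 to 197. The scores of these lists were 0.23, 0.29 and 0.20 in library 2, and library 3 had the lowest, at -0.26, -0.36 and -0.23. Library 4 was highest for 1, 4 and 7 genes of these lists, among them Fabp3 (475 FPKM), Cox6a2 (2074) and Cox8b (1510). Under median-of-ratios scaling the scores of fatty acid oxidation and of oxidative phosphorylation were highest in library 4 in place of library 2, and without library 3 oxidative phosphorylation lay at percentile 94.1 and fatty acid oxidation at 99.7, with a score SD of 0.16 in place of 0.24. The 14 fast sarcomere genes lay at percentile 94.0, with the lowest score, -0.22, in library 2. They passed the 95th percentile under 5 alternatives, among them median-of-ratios scaling (percentile 99.7). The 13 mitochondrially encoded messenger RNAs were highest in library 3 for 8 genes and in library 2 for 5 (percentile 99.0).

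Genes of embryonic and regenerating muscle were highest in library 3. Of the 12 genes, 11 had their highest level there, and the list score was 1.50 in library 3 against -0.47 to -0.22 elsewhere (SD 0.84, percentile 100). On the log2(FPKM + 1) scale this corresponds to 3.30-fold over the next library. Mymk, which encodes the myoblast fusion protein myomaker (chromosome 2, 27061636 to 27072179), was at 22.1 FPKM in library 3 and between 0 and 1.05 in the others. The embryonic light chain gene Myl4 was at 30.4 against 1.65 to 2.85 FPKM, Myh3 at 16.3 against 1.43 to 4.47, the stress-responsive Ankrd1 at 30.2 against 3.56 to 6.42 and the myogenic regulator Myog at 30.1 against 6.45 to 11.4. Actc1, the cardiac actin of developing muscle, was at 116 against 23.3 to 75.6 FPKM. The denervation and neuromuscular junction list followed, with 8 of 13 genes highest in library 3 and a score of 0.69 against -0.25 to -0.06 (SD 0.39, percentile 100), and its acetylcholine receptor gene Chrna1 was at 14.99 against 4.47 to 5.51 FPKM. Its other abundant genes were closer together, with Chrnb1 at 25.9 ± 6.45 FPKM and Rapsn at 18.2 ± 3.01 (SD, n = 5). Gadd45a, also in this list, was highest in library 4 at 24.6 FPKM against 14.3 to 14.8. Without library 3 the lists lay at percentile 62.9 and 36.4, so their spread rested on that library. The denervation list also fell to percentile 66.1 when only members at 10 FPKM or more were used.

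Macrophage, matrix, interferon and blood markers were highest in the same library. All 10 measured macrophage genes had their highest level in library 3 (score 1.25 against -0.57 to -0.08, percentile 100), among them Lyz2 at 172 against 29.7 to 46.8 FPKM, C1qa at 58.4 against 21.5 to 29.0, C1qc at 32.4 against 11.6 to 15.2 and Cd68 at 35.3 against 3.21 to 5.40. Of 20 extracellular matrix genes, 18 were highest there (percentile 100), with Col3a1 at 332 against 81.1 to 133 FPKM, Col1a1 at 456 against 218 to 318 and Sparc at 438 against 324 to 406. Of 19 interferon response genes, 17 were highest there (percentile 100, and 59.1 without library 3), with B2m at 128 against 68.7 to 80.3 FPKM and H2-D1 at 89.2 against 38.4 to 55.7. All 5 measured erythroid genes were highest there (percentile 100), with Hba-a1 at 590 against 210 to 312 FPKM; the haemoglobin genes have near-identical copies between which reads may be split. Of 29 cytosolic ribosomal protein genes, 27 were highest in library 3 (percentile 100), by small amounts, such as Rplp0 at 641 against 492 to 594 FPKM. Of 17 cachexia and inflammatory signalling genes, 12 were highest there (percentile 99.9), with the receptor Tnfrsf12a at 33.6 against 12.7 to 20.2 FPKM, while Cebpb was highest in library 4 at 39.7. The 6 measured cell cycle genes lay at percentile 98.1 and at 8.11 without library 3, with Pcna at 11.6 ± 1.50 FPKM (SD, n = 5). Without library 3 the score SD fell from 0.72 to 0.20 for macrophage, from 0.53 to 0.22 for matrix, from 0.71 to 0.31 for erythroid, from 0.24 to 0.15 for ribosomal protein and from 0.27 to 0.15 for cachexia genes, with percentiles from 96.1 to 99.99.

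**Figure D2:**
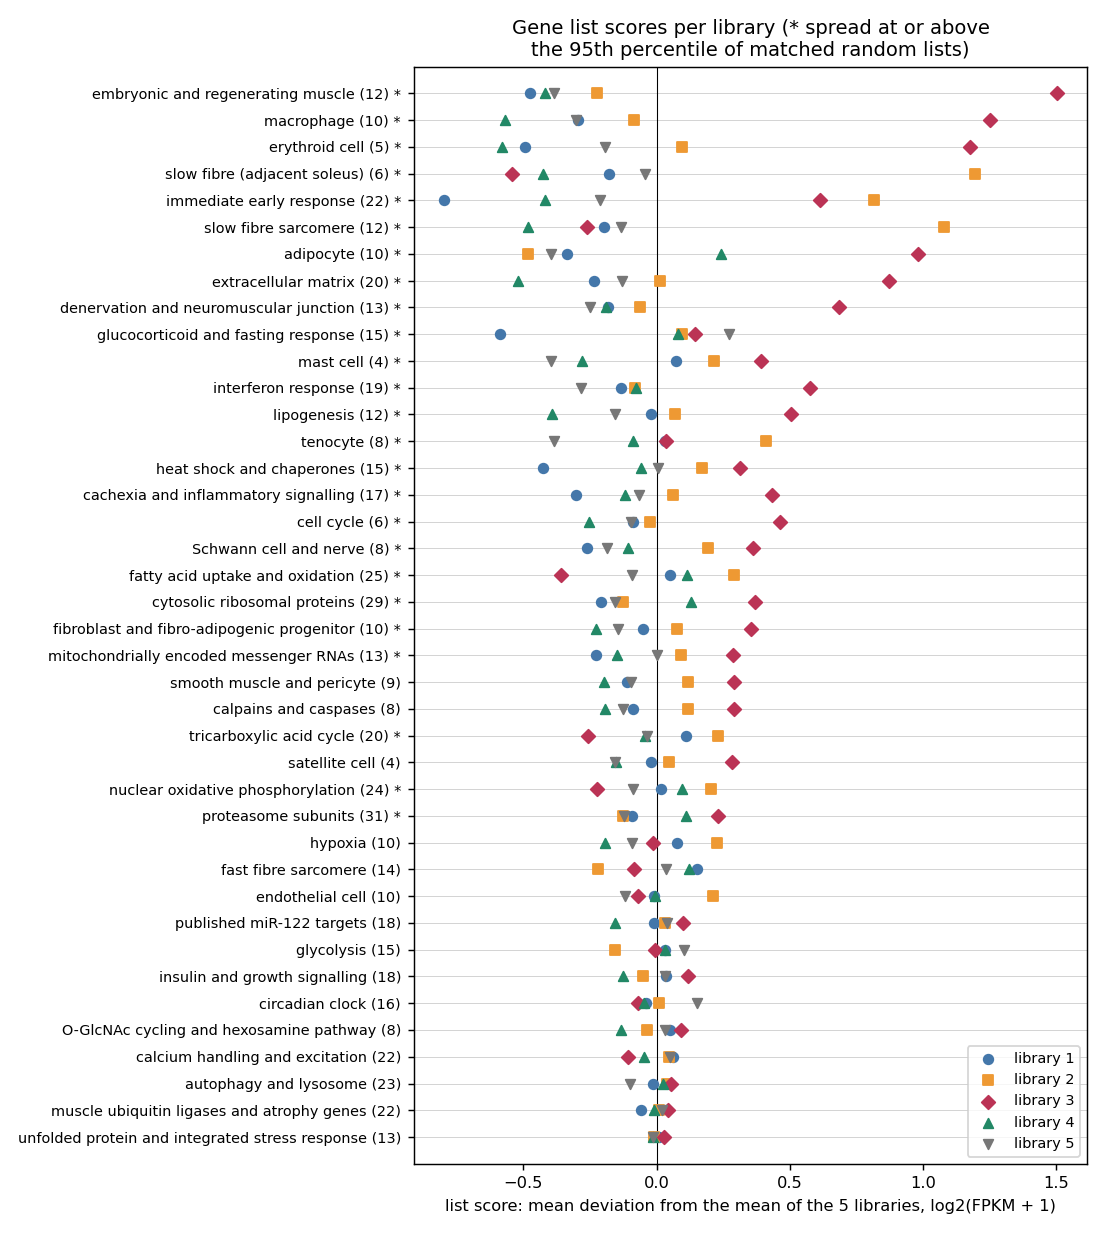
Scores of the 40 gene lists that could be scored (vertical axis, with the number of genes used) in each of the 5 libraries (points), as the mean deviation from the mean of the 5 libraries on the log2(FPKM + 1) scale (horizontal axis). Library 3 lies farthest to the right for embryonic and regenerating muscle (1.50) and macrophage (1.25) genes, and library 2 for slow sarcomere genes (1.08).

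Fat and lipid synthesis genes were also highest in library 3. Of 10 adipocyte genes, 8 were highest there (percentile 100), with the hormone gene Adipoq at 33.6 against 3.55 to 14.0 FPKM and Cfd at 203 against 29.8 to 109. Library 4 came next for both. Car3, which muscle fibres also express, was highest in library 1 at 3981 FPKM. Of 12 lipogenesis genes, 8 were highest in library 3 (percentile 99.99), and the desaturase gene Scd1 was at 153 against 18.2 to 37.6 FPKM, with Me1 at 41.4 ± 8.20 and Acacb at 32.4 ± 2.62 (SD, n = 5). Those 2 genes were not highest in library 3, with Me1 at 34.3 FPKM there against 30.9 to 48.5 and Acacb lowest at 28.4 against 31.0 to 34.4. Without library 3 the score SD fell from 0.62 to 0.36 for adipocyte genes (percentile 99.99) and from 0.33 to 0.20 for lipogenesis (percentile 99.8).

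Markers of the other resident cell types moved less. The 8 Schwann cell and nerve genes lay at percentile 98.2, and the 10 fibroblast genes at percentile 98.1, falling to 90.5 without library 3 and to 94.8 under median-of-ratios scaling. The 4 mast cell genes were all highest in library 3 (percentile 97.9, and 94.8 without library 5), with Tpsb2 at 10.7 ± 2.80 FPKM. The 8 tenocyte genes were highest in library 2 for 4 genes (percentile 99.3, and 91.4 without library 2 and 94.7 without library 5), with Fmod at 354 FPKM there against 170 to 264. The 9 smooth muscle and pericyte genes lay at percentile 94.8 and passed the 95th under 4 alternatives, with Acta2 at 44.6 ± 14.97 FPKM. The 4 satellite cell genes lay at percentile 74.5, at 36.4 without library 3 and at 96.5 with the median over members, with Sdc4 at 13.8 ± 3.28 FPKM. The 10 endothelial genes lay at percentile 72.5, at 8.86 without library 2 and at 91.7 with the median over members, and Cdh5 was at 26.7 ± 3.24 FPKM and Pecam1 at 24.7 ± 3.05 (SD, n = 5).

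Immediate early, heat shock and glucocorticoid response genes set libraries 2, 3 and 1 apart. The 22 immediate early genes had scores of 0.82 in library 2 and 0.61 in library 3 against -0.80, -0.42 and -0.21 in libraries 1, 4 and 5 (SD 0.69, percentile 100). The transcription factor gene Egr1 (chromosome 18, 34859823 to 34864984) was at 48.5 and 30.1 FPKM in libraries 2 and 3 against 1.47 to 6.08 in the others, and Fos at 40.4 and 25.7 against 2.61 to 3.17. Of the 22 genes, 12 were highest in library 2, 6 in library 3 and 4 in library 5. Nr4a1, the most abundant of them, was at 47.9, 157, 114, 117 and 158 FPKM in libraries 1 to 5, and so was highest in library 5. The list of 15 glucocorticoid and fasting response genes scored lowest in library 1, at -0.59 against 0.08 to 0.27 (percentile 100, and 51.6 without library 1). Tsc22d3 was at 35.5 FPKM in library 1 against 51.6 to 96.3, and Sgk1 at 33.2 against 42.0 to 72.8. Of the same list, Pdk4, Trim63 and Fbxo32 were instead lowest in library 3, at 44.8, 96.9 and 18.9 FPKM. The list of 15 heat shock genes also scored lowest in library 1, at -0.43 (percentile 99.98, and 94.9 without library 1). The small heat shock protein gene Cryab was at 948 and 1197 FPKM in libraries 2 and 3 against 402 to 476. Hspb6, the gene of that list with the highest mean, was lowest in library 4 at 620 FPKM, against 653 in library 1.

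In all, 25 of the 40 scored lists lay at or above the 95th percentile. Of these 25, 17 scored highest in library 3, 7 in library 2 and 1 in library 5. Lists of genes drawn at random would give 2, but genes of a real list can vary together, so 2 is not the number expected of real lists. The highest library was the same for 22 of the 25 under median-of-ratios scaling, the exceptions being the proteasome, fatty acid oxidation and oxidative phosphorylation. Without library 3, 22 lists lay at or above it. Many lists share a direction in the same libraries and are not independent of each other.

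Markers of lymphocytes were near 0, apart from 1 gene. The highest mean among T cell markers was 0.273 FPKM for Cd4, and among natural killer cell markers 0.0915 for Nkg7. Among B cell markers, Ighm, the constant region of the immunoglobulin mu heavy chain (chromosome 12, 113418558 to 113422730), was at 113, 19.5, 17.9, 51.6 and 87.4 FPKM in libraries 1 to 5, while the other 6 markers had means of at most 0.286 FPKM. Prkdc and Il2rg, mutated in this strain, were at 0.420 ± 0.0579 and 0.0554 ± 0.0384 FPKM (SD, n = 5). Xist was at 3.86 ± 0.970 FPKM, and none of 4 genes of the Y chromosome exceeded 0.0420 FPKM in any library. The neutrophil marker S100a9 had a mean of 1.20 ± 1.21 FPKM, highest in library 2 at 3.22. Skin and mammary epithelium were each represented by a single gene with a mean of 1 FPKM or more, Krt10 at 2.45 ± 0.285 and Krt19 at 1.01 ± 0.346. Of the brown fat markers, Ucp1 was at 0.0555 FPKM, and only Cox8b and Cox7a1, which muscle also expresses, had a mean above 1 FPKM, while Cidea reached 1.72 FPKM in library 2 and 1.19 in library 3. These lists had fewer than 4 genes at a mean of 1 FPKM and were not scored.

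At the level of single genes, the largest spread relative to abundance was that of Egr1, Sln, Fos, Slc25a25, Rrad, Postn, Mymk, Egr3, Timp1, Tubb6, Mt2, Arrdc2, Rpl3-ps1, Myl4, Mustn1, Apold1, Csrp3, Cd68, Hp and Adipoq. Sln, the sarcolipin gene whose product binds the calcium pump, was at 225 FPKM in library 2 against 7.88 to 24.2 in the others. The matrix protein gene Postn was at 61.7 FPKM in library 3 against 2.72 to 6.13, Timp1 at 34.4 against 1.62 to 3.42, the tubulin gene Tubb6 at 146 against 12.0 to 16.2, Rrad at 49.8 against 1.92 to 6.78 and the metallothionein gene Mt2 at 94.8 against 5.73 to 35.6. Csrp3 was at 456 and 286 FPKM in libraries 3 and 2 against 56.8 to 173. Rpl3-ps1, at 46.9 FPKM in library 3 against 2.99 to 5.38, is annotated as a pseudogene of Rpl3 and may share reads with it. Of the 64 genes with an SD of at least 1 on the log2 scale, 46 had library 3 as the farthest from their mean, above it.

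**Figure D3:**
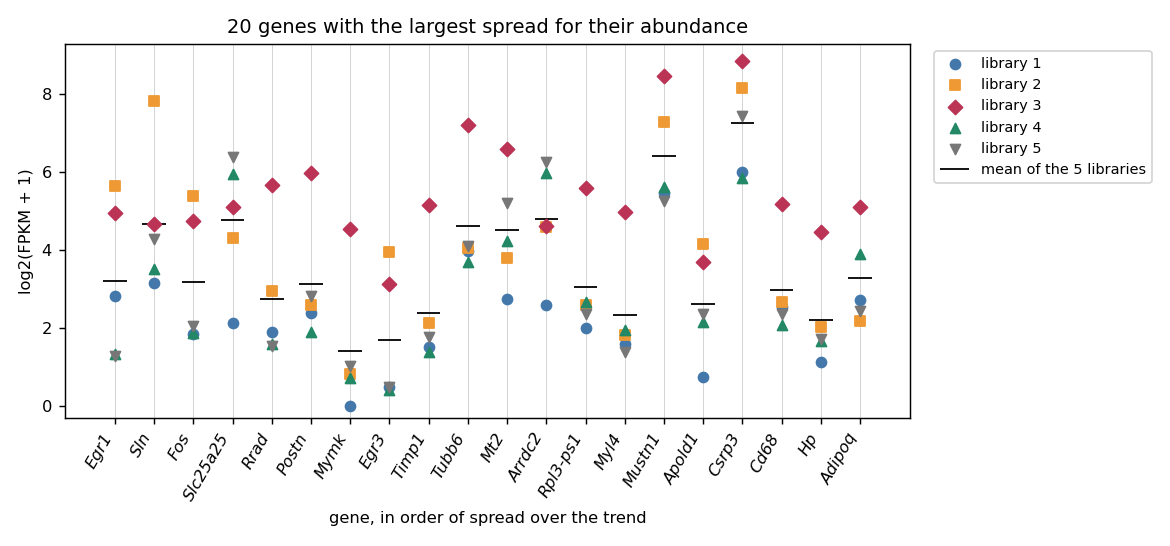
Level of the 20 genes with the largest spread relative to abundance (horizontal axis) in each of the 5 libraries (points) on the log2(FPKM + 1) scale (vertical axis), with the mean of the 5 libraries as a line. Library 3 is highest for Postn at 61.7 FPKM and library 2 for Sln at 225 FPKM.

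None of 10710 genes passed an adjusted p of 0.05 in limma's F test of a gene's variance against the trend for its abundance, with 616 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.640. With voom weights on the recovered reads the count was also 0, with 580 at an unadjusted p under 0.05. Without library 3, Egr1, Sln and Slc25a25 (each at an adjusted p of 0.0353) and Arrdc2 (0.0494) passed in limma. The test had little power on these data. In data simulated on these genes it recovered 0% of 200 genes given 8 times the SD. It recovered 51% of those given 64 times, with 0 false calls. Its prior degrees of freedom, 3.93, were fitted to the spread of these same gene variances. A count of 0 therefore says little about how alike the libraries were.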

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

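Each value in this part named as a gap is the distance of the highest or lowest library from its nearest neighbour, divided by the range of the 5 libraries, on the log2(FPKM + 1) scale for genes, scores and ratios and in percent for shares, where above 0.71 passes Dixon's 95% limit, which chance passes about 1 time in 20. Of the tests weighed here, only the one on depth was chosen before its result was seen; the tests on slow muscle, heavy chain genes, fat, nerve and connective tissue and the share of fibre RNA replaced or changed earlier versions whose results had been seen. The labels give 1 group, so no biological explanation from the design was tested, and those weighed concern the tissue, cells and reads in the libraries.

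Library 3 lay above the others for embryonic and regenerating muscle (gap 0.873), denervation and neuromuscular junction (0.8), interferon response (0.758) and macrophage genes (0.734), and for the share of Myh3 (0.753). Counting error at the depth of library 3 did not account for it. After thinning all libraries to 16674504 reads in 20 draws, the score of regenerating muscle in library 3 still exceeded the next library by 1.72 on the log2 scale, as at full depth. Such thinning leaves the expected level of each gene unchanged, so it covers counting error only and no other effect of a smaller library. A lower share of muscle fibre RNA would raise other cell types alike, which argues against it as the whole cause, since the median deviation of macrophage genes from their mean over the 5 libraries exceeded that of endothelial genes by 1.14, with medians of 1.04 and -0.10, and the lower quartile of the former (0.99) lay above the upper quartile of the latter (0.01). It stays open in part, since the medians of smooth muscle (0.23), nerve (0.42), mast cell (0.42), erythroid (1.05) and adipocyte genes (1.39) were also above 0. A tissue that brought the transcripts of the regenerating muscle list along with its own would leave as large a fraction of them in the other libraries. In libraries 1, 2, 4 and 5 these genes had medians of 0.177 to 0.268 of their level in library 3, against 0.542 to 0.835 for nerve genes and 0.686 to 0.878 for fibroblast genes. The smallest differences within a library were 0.365 and 0.503, with quartiles apart in each. That argues against nerve, or connective tissue as marked by the fibroblast genes, as the source of these transcripts. The comparison assumes that the transcripts of a tissue keep their proportions between libraries. The extracellular matrix list was not compared in this way, and its median deviation in library 3 was 0.67, with 19 of 20 genes above 0. Fat stays open as a source, since adipocyte genes had medians of 0.179, 0.165 and 0.211 in libraries 1, 2 and 5 and the smallest difference was -0.103, although library 4 went against it (0.456 against 0.183, quartiles apart). Injured or regenerating muscle in that piece may account for the pattern and remains open, as do a change in the macrophages and differences between animals or in the handling of the tissue.

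Library 2 lay above the others for slow sarcomere genes (gap 0.777), for the 6 soleus markers among them (0.711) and for the share of Myh7 (0.865). The scaling of library 2 did not account for it, because slow and fast sarcomere scores in it differed by 1.3 on the log2 scale and a common factor moves both alike. More slow or red muscle in that piece stays open. Of 45 tricarboxylic acid cycle and fatty acid genes, none of them in the sarcomere list, 34 were highest in library 2, a count known before the test was written, but under median-of-ratios scaling 24 were, and the fatty acid score was highest in library 4. Those values also do not separate tissue of a neighbouring muscle, or of another part of the gastrocnemius, from a different fibre composition of the same muscle.

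Ighm was present at 17.9 to 113 FPKM in a strain without mature B cells. Intact B cells would bring their other transcripts, but the highest mean among the other 6 B cell markers was 0.005 of that of Ighm. Of 6 other heavy chain constant region genes in the table, 5 were listed at 0 in every library, and the highest, Ighg2c, had a mean of 0.0057 of that of Ighm. How reads that match several genes were treated is not given, so these values cannot exclude shared reads. The source of the Ighm reads within the gene stays open, because values per gene do not show where in it the reads lie.

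The remaining results are given as values. The glucocorticoid and fasting list was lowest in library 1 (gap 0.779), and the ratio of Gfpt1 to Gfpt2 was highest in it (0.717). Of 202 genes examined, 26 passed, and 18 of them were high in library 3. The genes examined include the 20 with the largest spread and 17 chosen after their values were seen, so the count was not compared with chance. These 18 were Ankrd1 (0.747), B2m (0.749), Lyz2 (0.744), C1qc (0.743), Igkc (0.794), Cd4 (0.841), Trbc2 (1), Klrk1 (0.752), Postn (0.769), Mymk (0.771), Timp1 (0.799), Tubb6 (0.885), Rpl3-ps1 (0.812), Myl4 (0.849), Cd68 (0.806), Hp (0.731), Chrng (0.959) and Chrna1 (0.838). Igkc, Cd4, Trbc2 and Klrk1 had means of at most 0.273 FPKM. Tnnt1 (0.713), Tnnc1 (0.849) and Ucp1 (0.774), the last with a mean of 0.0555 FPKM, were high in library 2, and Mylpf (0.716) was low in it. Fbxo32 (0.714) was low in library 3 at 18.9 FPKM against 31.2 to 38.03. Gadd45a (0.943) was high in library 4 at 24.6 FPKM against 14.3 to 14.8. Nr4a1 (0.724) was low in library 1 at 47.9 FPKM against 114 to 158. Kdm5d (1) was above 0 in library 1 alone, at 0.00547 FPKM. No library measure passed, among them the total and the mitochondrial share.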

How the results depend on the processing

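Voom weights, the filter at 10 FPKM in every library, the exclusion of mitochondrial genes and the myosin shares from reads were chosen after the data were seen; the other alternatives were planned. The count of genes varying between libraries ranged from 0 to 4 when a library was left out. It was 4 without library 3, where the prior of the variance had 5.75 degrees of freedom in place of 3.93, and 0 under every other alternative run; the cause was not tested. At an unadjusted p the count was 616, and 562 to 671 under the alternatives that tested a similar number of genes, 905 without a filter and 239 and 204 under the stricter filters. Of the genes detected in all 5 libraries, 9678 at 1 FPKM, 5163 remained at a threshold of 5 FPKM because fewer genes reach it. The number of lists at or above the 95th percentile was 25, and 20 to 30 over the alternatives. Of 353 list values under alternatives, 324 stayed on their side of that percentile, 15 fell below it and 14 rose above it, and the lists that crossed it are named beside their results. All 91 mean values of the 13 ratios kept their sign. For a pair with the same order in all 5 libraries, neither a library left out nor the pseudocount could change the sign. Some values moved far. On recovered reads, which are not corrected for gene length, Fbxo32 to Trim63 went from -2.03 to -0.19, Igf1 to Mstn from -1.66 to -0.51, Foxo1 to Foxo3 from -0.45 to -0.87, Gfpt1 to Gfpt2 from 0.39 to 1.55, Ryr1 to Cacna1s from 0.73 to 2.03 and Il6st to Il6ra from 3.09 to 5.14, and Gfpt1 to Gfpt2 was 0.25 without library 1. All 36 mean values of the myosin shares stayed within 1 SD, an SD that is itself large for the rarer isoforms, as Myh3 fell from 0.0634% to 0.0286% without library 3 and Myh7 from 1.45% to 0.924% without library 2. Leaving out 1 of 5 values cannot move a mean by 1 SD, so only the shares from reads could have moved farther. The share of Myh4 was 73.1% to 82.3% with a library left out, the highest without library 2. The median correlation of libraries was 0.973 to 0.990. Median-of-ratios scaling shifted libraries by -0.12 to 0.08 on the log2 scale, and the highest library changed under it for the proteasome, fatty acid and oxidative phosphorylation lists. The alternatives planned for a table of counts (a count test with other size factors, its filters and dispersion outliers) were not run, nor were 2 that equal the deposited values, scaling by the library total and myosin shares divided by gene length. No paired analysis was possible because the labels give 1 group. Depth limits genes near 1 FPKM, where the lowest had 2.2 reads per library on average.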

Other observations

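Slc25a25, a calcium-dependent mitochondrial ATP and phosphate carrier, was at 61.1 and 83.2 FPKM in libraries 4 and 5, at 18.8 and 33.4 in libraries 2 and 3 and at 3.39 in library 1. Arrdc2 was likewise at 61.5 and 75.03 FPKM in libraries 4 and 5, 23.0 and 23.4 in libraries 2 and 3 and 5.00 in library 1. After these values were seen, 4 further genes with high levels in libraries 4 and 5 were picked. Ppp1r3c, a glycogen-targeting subunit of protein phosphatase, was at 128 and 215 FPKM there against 36.0 to 72.6 in the others, and Gadd45g at 76.1 and 79.3 against 12.4 to 41.5. Klf10 was at 27.95 and 24.5 FPKM against 5.06 to 11.3. Pcx, the pyruvate carboxylase gene, was at 131 and 173 FPKM against 28.2 to 65.9. Egr1 was at its lowest in these libraries, at 1.53 and 1.47 FPKM.

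Chrng, the fetal gamma subunit of the muscle acetylcholine receptor, was chosen after its values were seen. It was at 10.2 FPKM (474 reads) in library 3 and at 0.0302 to 0.136 FPKM (2 to 8 reads) in the others. The adult subunit gene Chrne was at 10.95 ± 0.744 FPKM (SD, n = 5). Among the 12 genes of the embryonic and regenerating muscle list, Igfn1 was the exception, with its highest level in library 5 at 2.20 FPKM.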
